A study of Rattus norvegicus with 5 samples.

How the data were processed

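Single-cell 3' RNA libraries labelled as from dissociated rat lungs were compared, 3 labelled SuHx and 2 labelled VeNx. Per the submitters' processing notes, the authors made UMI counts per gene and barcode with Cell Ranger on the rat assembly mRatBN7.2, and per the file headers the version was Cell Ranger 7.1.0. The deposited matrices hold whole-number counts of UMIs, not normalized, for 42172 genes, of which 30237 had at least 1 UMI in the barcodes kept. The files do not say whether reads in introns were counted. Gene symbols were taken as the files give them. The 13 protein genes of the mitochondrial genome had 0 UMIs in every library, so the mitochondrial percent rests on the ribosomal RNA genes mt-Rnr1 and mt-Rnr2.

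Barcodes with at least 500 UMIs, at least 200 genes and under 20% mitochondrial UMIs were kept; 287 of 83575 failed. Doublets were called in each library by a nearest-neighbour score against simulated doublets, which marked 6128 barcodes (8.72% of SuHx 1, 8.30% of SuHx 2, 4.23% of SuHx 3, 8.33% of VeNx 1 and 3.18% of VeNx 2), and these were left out. The threshold marked 47.8% (VeNx 2) to 61.8% (VeNx 1) of the simulated doublets. Rates expected from the number of barcodes were 19.0%, 17.4%, 9.20%, 14.5% and 6.71% in the same order, so doublets may remain among the cells kept. The 77160 cells kept were 21596, 19970 and 11006 in SuHx 1, SuHx 2 and SuHx 3 and 16604 and 7984 in VeNx 1 and VeNx 2. Median UMIs per barcode were 9732.5, 7990, 2672, 10980.5 and 5050.5 and median genes 3470, 3080, 1578, 3674 and 2120 in the same order. Cells of all libraries were clustered together without integration (3000 variable genes, 40 principal components, 20 nearest neighbours, Leiden at resolution 1 with leidenalg 0.10.2 and igraph 0.11.9). A cluster was named after 1 of 25 cell classes from markers fixed before the data were examined. It stayed unnamed when under 3 markers were detected or another class led its top 10 genes. So did a cluster with a weak marker score, or with an unrelated class scoring nearly as high. Clusters of cells with few UMIs for their library stayed unnamed when they had few markers or none among the top 10 genes. The unnamed clusters held 11.2%, 5.9%, 27.0%, 4.2% and 5.0% of the cells of SuHx 1, SuHx 2, SuHx 3, VeNx 1 and VeNx 2. Endothelial cells were subclustered in the same way (2000 variable genes, 20 principal components, 15 neighbours) and named by subtype markers. Names rest on markers alone and were not checked against an annotation by the authors. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

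Cells are not replicates, so UMI counts were summed per library and class, for libraries with at least 20 cells of the class and classes with at least 2 such libraries in each group. The sums were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM normalization, filterByExpr by group) with Benjamini-Hochberg adjustment within a class, and a gene was called at an adjusted p under 0.05. Log2 fold changes are SuHx over VeNx on edgeR's scale with its default prior count of 0.125. The ± after a log2 fold change is an approximate standard error (SE) derived from the test. It is the absolute log2 fold change over the square root of edgeR's F statistic. The classes described in full are endothelial, fibroblast, mural, AT2, alveolar macrophage, interstitial macrophage, monocyte and T. AT2 cells and alveolar macrophages reached 20 cells in SuHx 1, SuHx 2 and both VeNx libraries, and aerocytes in too few libraries to be fitted. CPM values are UMI counts of a gene scaled to the total of the class in the library.

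The genes named were chosen by a rule fixed before the data were examined: in each class, up to 10 called genes per direction with the largest log2 fold change, a mean log2 CPM of at least 3 and CPM that do not overlap between the groups, leaving out symbols that are only identifiers, ribosomal, mitochondrial, sex-linked and marker genes; called members of lists that pass, up to 10 per list; in endothelial cells also Kdr, Flt1, Bmpr2, Acvrl1, Eng, Id1, Edn1 and Nos3, called or not; and where a class has no called gene, the 3 smallest p in each direction. By chance alone 33.3% of genes do not overlap between 2 and 2 libraries and 20% between 3 and 2. Where a group had 0 UMIs of a gene, the fold is a lower bound against a floor of 3 UMIs over the group; with 1 to 3 UMIs it is the ratio with an exact 95% counting interval. Both cover counting error only.

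In all, 33 gene lists fixed before the data were examined were tested with limma's camera (limma 3.58.1, voom log2 CPM) at a preset correlation of 0.01, in classes where at least 5 members were tested, with adjustment over the lists of a class, and again with the correlation estimated. Shares of kept cells per class and of endothelial cells per subtype (libraries with at least 50 endothelial cells) were compared with a two-sided exact permutation test of the difference of means. The interaction of class and group was fitted over the endothelial and fibroblast sums with the library as a covariate.

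Because the library labelled SuHx replicate 3 held heart muscle genes and lacked lung epithelial genes, every fit was repeated on the other 4 libraries with the same settings. That choice, the interaction, subclustering without SuHx 3, the C1q cluster alone, a list of mast cell genes and the lists of cardiomyocyte and lung epithelial genes were made after the data were seen. So were the tests of that library, of the mix of endothelial subtypes and of other classes among fallen genes, and the choice of the genes said to be named after their values were seen. The other choices were made before. The alternatives were DESeq2 1.42.0, relative log expression size factors, no filter on low counts, a minimum log2 fold change of 1, each library left out in turn, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, resolution 2, each library clustered on its own, sums thinned to equal depth, at least 50 cells per library, and fry in place of camera.

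The fits were tested on simulated sums. Every count was drawn anew from a negative binomial count model, with the pooled mean and the estimated dispersion of the gene in the real sums. In these, 200 genes were changed 2, 4 or 8-fold, and the others were unchanged and independent, so the rates describe that model. In endothelial cells of the 4 other libraries (11607 genes) edgeR recovered 14.9%, 80.6% and 98.5% of genes changed 2, 4 and 8-fold, with 10 false among 139 calls, and 0% of each in all 5 libraries (12529 genes). In mural cells of the 4 other libraries (10844 genes) it recovered 20.9%, 83.6% and 97% with 12 false among 146 calls, in alveolar macrophages (18564 genes) 13.4%, 53.7% and 75.8% with 5 false among 100, and in T cells of the 4 other libraries (14111 genes) 22.4%, 74.6% and 97% with 29 false among 158. In all 5 libraries edgeR recovered 0% of each in mural cells. In T cells of all 5 it recovered 0%, 0% and 12.1% of genes changed 2, 4 and 8-fold. A count of 0 called genes in these fits thus cannot show that genes were unchanged. No pair of libraries was a duplicate: at least 66.6% of genes differed by more than 3 counting standard deviations in each pair.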

Results

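Messenger RNA was counted in single cells of 5 droplet libraries, labelled as from dissociated rat lungs. In SuHx, 3 libraries, rats received sugen-5416 (SU5416, an inhibitor of the VEGF receptors) with hypoxia for 3 weeks and then spent 3 weeks in normoxia, a treatment used in rats to model pulmonary arterial hypertension. In VeNx, 2 libraries, rats received vehicle in normoxia. The libraries SuHx 1, SuHx 2 and SuHx 3 held 295858807, 257142788 and 41767558 UMIs in 23708, 21810 and 11503 barcodes, and VeNx 1 and VeNx 2 held 279979463 and 76653302 UMIs in 18170 and 8384 barcodes. The median UMI count per barcode ranged from 2672 in SuHx 3 to 10980.5 in VeNx 1. The labels do not say whether the libraries come from separate animals, so p-values measure the spread between these libraries.

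Genes of lung epithelium and of heart muscle were compared between libraries to see whether each held the tissue its label names. The library labelled SuHx replicate 3 held the cardiomyocyte genes Ttn at 10600 CPM, Ryr2 at 8025 CPM and Myh6 at 1534 CPM, and the median of 10 cardiomyocyte genes was 650.2 CPM there and at most 0.484 CPM in the other 4 libraries. The club cell gene Scgb1a1 was at 0.0958 CPM in it and at 53140 to 79510 CPM elsewhere. The surfactant gene Sftpc was at 0.12 CPM in it and at 1334 to 12660 CPM elsewhere. The median of 10 lung epithelial genes was 0.0359 CPM in it and 297.1 to 725.8 CPM in the others. Genes of ribosomal proteins took 0.424% of its UMIs and 10.1 to 12.8% elsewhere, in files that do not say whether reads in introns were counted. Y-linked genes had a median of 0.0838 CPM against 38.3 to 56.0 CPM. Its endothelial cells, fibroblasts, mural cells, interstitial macrophages and T cells lay almost wholly in clusters that held few cells of any other library. It had no alveolar epithelial type 2 (AT2) cells or alveolar macrophages. It had no NK cells either in the clusters used here, though it entered the NK fits at resolution 2 and with each library clustered on its own. Each comparison is therefore given for all 5 libraries, as fixed beforehand, and for the 4 other libraries (2 SuHx against 2 VeNx), a fit chosen after these values were seen.

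**Figure D1:**
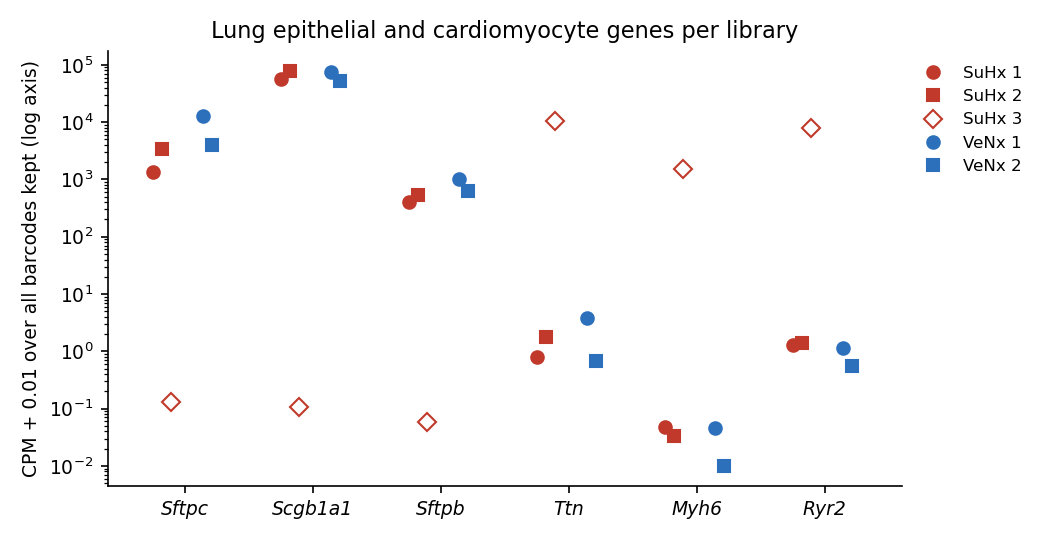
CPM (log axis, 0.01 added) of lung epithelial and cardiomyocyte genes in each library, with filled red points for SuHx 1 and SuHx 2, an open diamond for the library labelled SuHx replicate 3 and blue points for VeNx. The open diamond lies at 10600 CPM for Ttn and at 0.12 CPM for Sftpc.

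The shares of cell classes were compared to see which cells were more or less frequent in SuHx lungs. In the 4 other libraries, interstitial macrophages made up 6.36% ± 0.199 (SD, n = 2) of kept cells in SuHx and 2.06% ± 0.985 (SD, n = 2) in VeNx. Mast cells or basophils made up 1.88% ± 0.863 and 0.0151% ± 0.0213. B cells made up 5.83% ± 0.052 in SuHx and 10.2% ± 0.292 in VeNx. NK cells were at 2.29% ± 0.30 and 5.65% ± 3.19, and AT2 cells at 1.25% ± 0.593 and 3.97% ± 3.21. The groups did not overlap for these 5 classes. They did not overlap for 9 of 21 classes, unnamed cells included, where chance gives 33.3% of classes. That of AT2 cells rests on VeNx 1 (6.24%, against 1.70% in VeNx 2 and 1.67% in SuHx 2), and was lost without alveolar macrophages in the total, under the stricter cell filter and at resolution 2. The exact permutation test (two-sided, 6 splits) cannot go below p = 0.333. Endothelial cells were at 2.20% and 2.33%, fibroblasts at 1.43% and 1.34%, and mural cells at 1.28% and 0.978% in SuHx and VeNx. Alveolar macrophages were at 28.5% ± 10.4 and 21.8% ± 7.80, a difference within the spread of the libraries, as was that of T cells (9.83% and 13.7%). In edgeR's test on cell numbers, mast cells or basophils were higher in SuHx with a log2 fold change of 6.60 (edgeR adjusted p = 0.0276 in the 4 other libraries, 0.876 in all 5). In all 5 libraries interstitial macrophages were at 6.28% ± 0.198 and 2.06% (exact permutation p = 0.1, the smallest that 10 splits allow). That order counts SuHx 3 as lung. For AT2, B and NK cells SuHx 3 lay lowest, at 0%, 0.954% and 0%, so the order of the 5 libraries says nothing of SuHx there.

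**Figure D2:**
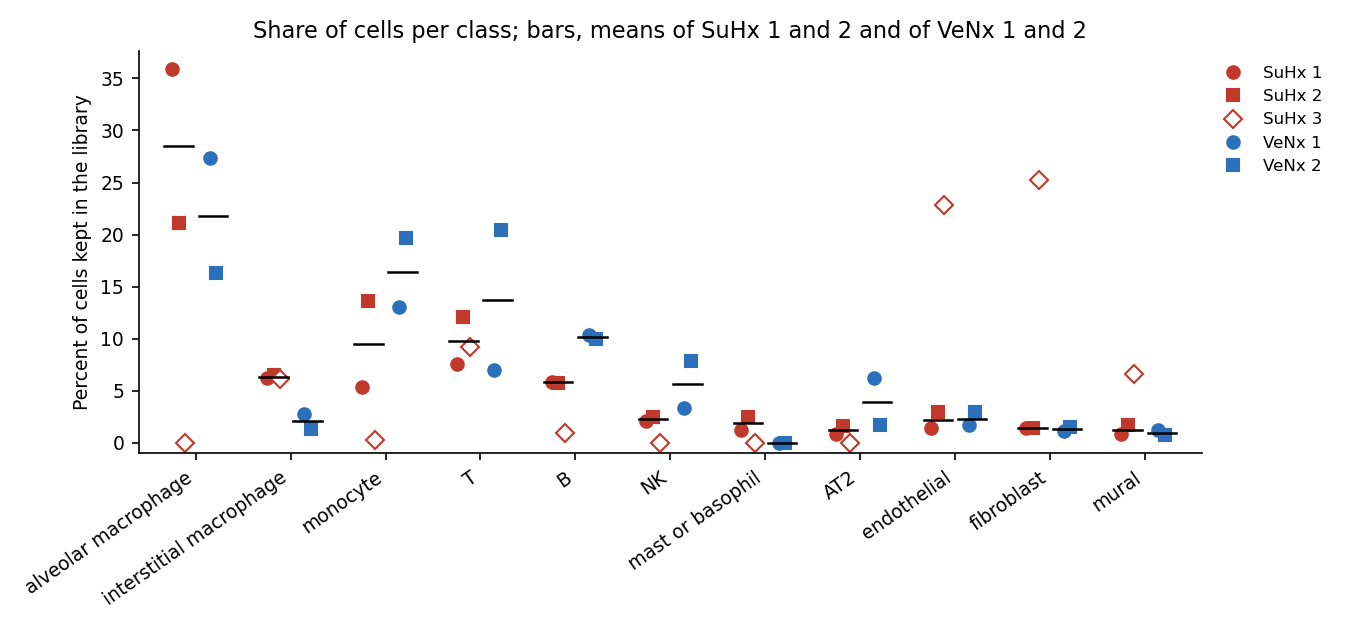
Percent of kept cells per class, 1 point per library (filled red SuHx 1 and SuHx 2, open diamond SuHx 3, blue VeNx), with bars at the means of SuHx 1 and SuHx 2 and of VeNx. Interstitial macrophages had means of 6.36% in SuHx and 2.06% in VeNx.

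Endothelial cells line the vessels and carry the receptors that SU5416 blocks, and the comparison asks which of their genes differed between SuHx and VeNx lungs. In the 4 other libraries, the basement membrane genes Nid2 (log2 fold change 4.00 ± 0.33, SE, n = 2 and 2, as for every log2 fold change of these libraries), Vwa1 (4.31 ± 0.44), Col18a1 (3.23 ± 0.51) and Hspg2 (2.00 ± 0.16) rose in SuHx, while the basement membrane collagen Col4a3 fell (-3.45 ± 0.35). Igfbp3 (3.45 ± 0.43), the glycolytic enzyme Pgk1 (2.90 ± 0.24) and the cell cycle inhibitor Cdkn1a (2.50 ± 0.30) also rose, with an edgeR adjusted p of 0.0233, 0.0122 and 0.0219. The type II BMP receptor Bmpr2 fell from 1803 and 2213 CPM in the VeNx libraries to 573.1 and 714.8 CPM in the SuHx libraries (log2 fold change -1.60 ± 0.21, edgeR adjusted p = 0.0259). Its partner Acvrl1 fell by 1.39 ± 0.20 on the log2 scale (edgeR adjusted p = 0.0305). In all 5 libraries Bmpr2 and Acvrl1 had log2 fold changes of -1.47 and -1.55, and neither was called. Serpina1 (-5.91 ± 0.79), Kcnk2 (-5.14), Smarca1 (-4.34), Lrrn1 (-3.83), Bank1 (-3.81) and Vipr1 (-3.49) were among the named genes with the largest falls. Hoxd9 had 147 UMIs in SuHx and 0 in VeNx, at least 15.2-fold higher with the floor at 3 UMIs over the group. Ecel1 was 73.1-fold higher (95% exact counting interval 20.1 to 605.1) and Serpina3n 68.1-fold (18.7 to 564.0), at 8.52% of its level in fibroblasts.

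Among the VEGF receptors of endothelial cells, Kdr had a log2 fold change of -0.63 and Flt1 of -0.36 (edgeR adjusted p = 0.347 for both), and neither was called. Eng was at 0.03, Id1 at -0.10, Edn1 at 0.46 and Nos3 at 0.70 on the log2 scale, and none of these was called (edgeR adjusted p = 0.934, 0.846, 0.425 and 0.119). The hypoxia-inducible factor Hif1a rose by 1.03 and Epas1 fell by 1.34 on the log2 scale.

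Across endothelial genes, edgeR called 441 of 11607 in the 4 other libraries, 178 higher and 263 lower in SuHx, and DESeq2 called 721. In all 5 libraries edgeR called 0 of 12529 (619 at an unadjusted p under 0.05) and DESeq2 88. The CPM of all 70 called genes that the naming rule selected do not overlap between the groups, so leaving out a library could hardly turn a direction. All 70 genes kept theirs when each library was left out in turn. Of these, 27 stayed called every time, among them Nid2, Vwa1, Col18a1, Hspg2, Igfbp3, Pgk1, Cdkn1a, Serpina1 and Kcnk2. The count was 201 without SuHx 1, 771 without VeNx 1 and 293 without VeNx 2. With each library clustered on its own edgeR called 0 genes (2271 at an unadjusted p under 0.05), and all 70 named genes kept their direction. With called doublets kept it called 111, 54 higher and 57 lower, and 28 of the 70 named genes stayed called. Bmpr2, Acvrl1, Ecel1, Hoxd9, Mx1, Usp18, Oas2, Slc2a3, Gapdh, Ldha, Ccng1, Phlda3 and Bax did not stay called in every fit leaving out a library. Some risen genes were far below the level of another class: Mfap5 at 2.33% of fibroblasts, Col1a1 at 1.34% of fibroblasts, Tagln and Myh11 under 1% of mural cells, and Cpa3 and Mcpt8 under 1% of mast cells. Among fallen genes Bank1 lay at 7.03% of B cells and Col4a3 at 9.92% of alveolar epithelial type 1 (AT1) cells.

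**Figure D3:**
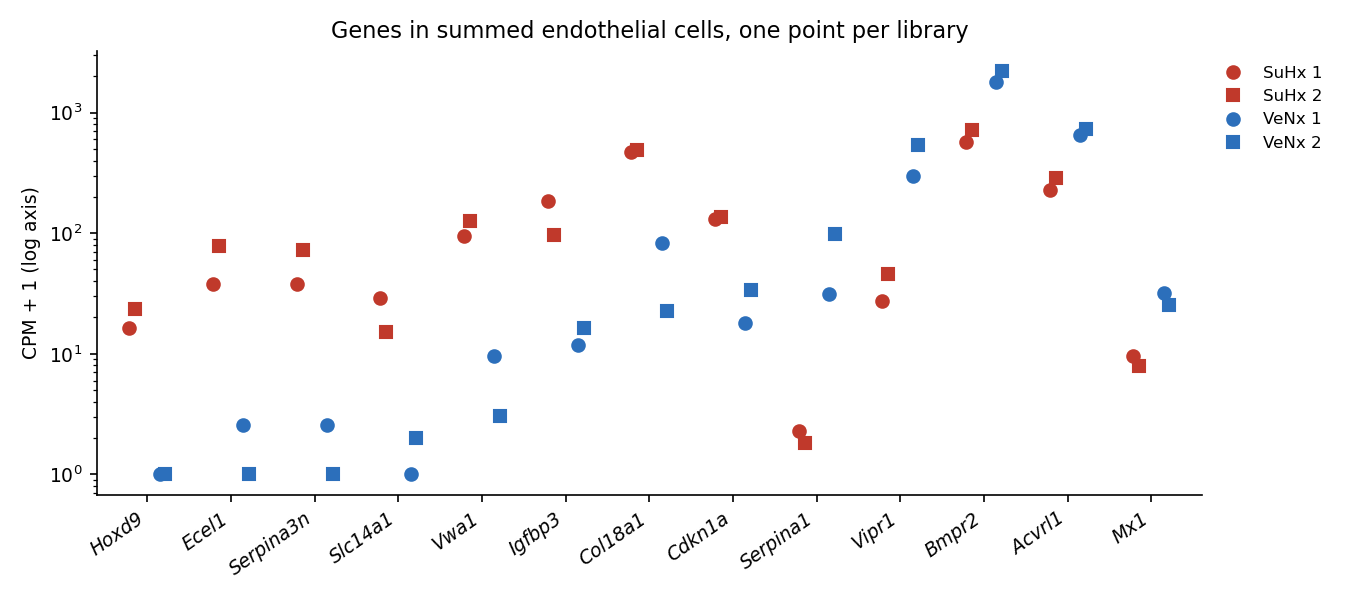
CPM (log axis, 1 added) of genes in endothelial cells of the 4 other libraries, 1 point per library, red for SuHx 1 and SuHx 2 and blue for VeNx. Bmpr2 was at 573.1 and 714.8 CPM in SuHx and at 1803 and 2213 CPM in VeNx.

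Fixed gene lists were tested in endothelial cells with camera at a preset correlation. The extracellular matrix list was higher in SuHx (10 of 40 members called higher and 1 lower, 27 and 1 adjusted over the list alone, adjusted p = 1.21e-13, adjusted p = 0.230 with an estimated correlation). The interferon response list was lower, with 11 of 39 members called lower and 29 adjusted over the list alone (adjusted p = 3.07e-15, adjusted p = 0.230 with an estimated correlation). Mx1 (log2 fold change -1.83), Herc6 (-1.90), Usp18 (-2.08) and Oas2 (-2.23) were among its called members. The glycolysis list was higher (5 of 21 members called, 10 adjusted over the list alone, adjusted p = 2.78e-07, adjusted p = 0.230 with an estimated correlation), with Slc2a3 (2.64, at 3.52% of its level in neutrophils), Gapdh (1.26) and Ldha (1.09) beside Pgk1. The list of cellular senescence and p53 genes was higher too (6 of 21 called, 7 adjusted over the list alone, adjusted p = 0.000106, adjusted p = 0.230 with an estimated correlation), with Ccng1 (2.31), Phlda3 (1.24) and Bax (1.09) beside Cdkn1a. The BMP and TGF-beta list (1 of 28 members called higher and 3 lower, 2 and 5 adjusted over the list alone) had an adjusted p of 0.839, and the VEGF and angiopoietin list (1 of 24 called higher and 2 lower, 2 and 6 adjusted over the list alone) of 0.109. Of 30 lists, 15 passed and 0 passed with an estimated correlation, where the smallest adjusted p was 0.230, and the same counts, 15 and 0, were found in all 5 libraries.

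Subtypes of blood endothelial cells were compared because capillary, arterial and venous cells carry different receptors. In the 4 other libraries, general capillary cells made up 21.0% ± 6.54 (SD, n = 2) of endothelial cells in SuHx and 49.1% ± 21.2 in VeNx, and arterial cells 45.9% ± 11.7 and 15.2% ± 1.18. The difference of general capillary cells was -43.2 percentage points without VeNx 1 and -13.2 without VeNx 2. The arterial subcluster with most cells of the 4 libraries, 196, is named by its marker score but led by Eya4, Frzb and matrix genes such as Fn1, Lox and Bgn, with no arterial marker among its top 10 genes. The arterial subclusters of 176 and 98 cells had no arterial marker among their top 10 genes either. Aerocytes, the large capillary cells of the alveoli, were at 8.84% ± 5.24 and 15.01% ± 10.5, a difference within the spread of the libraries. Venous cells were at 7.17% ± 0.168 and 12.6% ± 2.86. Endothelial cells left without a subtype name were at 17.1% ± 0.25 and 8.09% ± 6.67. A subcluster of 184 such cells was led by Ccl21 and Mmrn1, markers of lymphatic endothelial cells, so the total may not be blood endothelial cells alone. Subclustered anew without SuHx 3, general capillary cells were at 26.2% ± 4.42 and 40.8% ± 10.9, arterial cells at 29.5% ± 5.82 and 17.4% ± 4.00, and venous cells at 13.96% ± 2.01 and 14.24% ± 4.02 (exact permutation p = 1), so the difference of venous cells was lost. The largest arterial subcluster of the new run, 137 cells, was led by Bgn, Fn1 and Frzb. Its top 10 genes held the venous marker Selp and no arterial marker. With all libraries a subcluster of 176 cells led by Prnd, Nxph1, Igfbp3 and Gria2 was named arterial. In the new run these leading genes were split between subclusters. One of 65 cells led by Gria2, Chrm3, Prnd and Hoxd4 was named general capillary, and one of 85 cells led by Igfbp3 and Nxph1 arterial. The exact permutation test (two-sided, 6 splits) cannot go below p = 0.333 in these libraries. With all 5 libraries general capillary cells were at 22.9% ± 5.71 in SuHx (exact permutation p = 0.1, the smallest that 10 splits allow, with SuHx 3 counted as lung). The subclusters behind these shares are led in part by genes that differ between the groups, so the shares and the gene changes are not separate results. Serpina1, Kcnk2 and Rgs7 lead a general capillary subcluster mostly of VeNx cells, and Igfbp3 an arterial subcluster mostly of SuHx cells. Within general capillary cells alone, edgeR called 765 genes (369 higher and 396 lower, 1171 in all without VeNx 1) and DESeq2 393 in the 4 other libraries. In all 5 edgeR called 0 (558 at an unadjusted p under 0.05) and DESeq2 112. Of the 395 genes called in all endothelial cells and tested there, 393 had the same direction and 303 were called. General capillary cells of the groups lay in different subclusters: 1 held 18 and 60 cells of SuHx 1 and SuHx 2 and 91 and 144 of VeNx 1 and VeNx 2, another 32 and 91 against 5 and 7.

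Fibroblasts were compared to see which genes of the cells that make connective tissue differed. In the 4 other libraries the metallothionein Mt2A (log2 fold change 4.00 ± 0.30, edgeR adjusted p = 0.00855) rose in SuHx, as did Mt1 (3.46 ± 0.26), named after its values were seen, the metalloprotease Adam12 (4.51 ± 0.40) and the complement genes C6 (5.77 ± 0.44) and C4b (1.70). The chemokines Cxcl9 (4.24) and Cxcl12 (2.86), the interferon response genes Mx1 (3.47) and Irf1 (1.502), Chi3l1 (3.50) and the interleukin 1 receptor Il1r1 (1.61) rose too. Mrgprg (-4.05) and the nuclear receptor Esrrg (-1.48) fell. Mt1m was 27.4-fold higher (95% exact counting interval 7.40 to 228.8). C1qa, also called, lay at 1.17% of its level in interstitial macrophages and RT1-Db1 at 0.848% of that in dendritic cells.

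In fibroblasts edgeR called 25 genes in the 4 other libraries, 22 higher and 3 lower, and DESeq2 160. In all 5 libraries edgeR called 0 (297 at an unadjusted p under 0.05) and DESeq2 4. The count was 133 without SuHx 2 and 0 without VeNx 1 or without VeNx 2 (1666 and 1036 by edgeR at an unadjusted p under 0.05). None of the 18 named genes stayed called in every fit that left out a library, though all 18 kept their direction. The CPM of these 18 genes do not overlap between the groups, so leaving out a library could hardly turn a direction. The complement list was higher (2 of 20 members called, 12 adjusted over the list alone, adjusted p = 6.9e-12, adjusted p = 0.517 with an estimated correlation). The MHC class II list was higher (1 of 8 called, 8 adjusted over the list alone, adjusted p = 9.29e-11, adjusted p = 0.283 with an estimated correlation). So was the interferon response list (3 of 36 called, 3 adjusted over the list alone, adjusted p = 4.26e-06, adjusted p = 0.517 with an estimated correlation). Of 29 lists, 15 passed and 0 passed with an estimated correlation.

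Mural cells, named from markers of smooth muscle cells and pericytes, were compared because the vessel wall thickens in pulmonary hypertension. The markers do not separate smooth muscle of vessels from other smooth muscle, and a change in the mix of these cells was not tested. In the 4 other libraries the contractile genes Des (log2 fold change 1.97), Myl9 (1.52) and Tpm2 (1.14) rose in SuHx, with the cyclin Ccnd1 (4.43), Epas1 (1.76), the chemokine Cxcl1 (2.94), Il6 (2.60) and Igfbp7 (1.73). Thy1 was 97.4-fold higher (95% exact counting interval 26.9 to 805.6), Sbspon 31.6-fold (10.7 to 153.8), Dmp1 29.8-fold (10.1 to 145.2) and Ccl2 25.1-fold (6.86 to 209.3), at 2.25% of its level in mast cells. Tesc was at least 26.3-fold higher. The muscarinic receptor Chrm2 (-4.76 ± 0.36, edgeR adjusted p = 0.00124), PCOLCE2 (-4.89), Osr2 (-4.36), Cntfr (-4.24), Slitrk6 (-4.07) and Vegfa (-2.46 ± 0.35, edgeR adjusted p = 0.00373, at 4.39% of its level in AT1 cells) fell. Bmp8a was at least 27.3-fold lower and Corin 46.3-fold lower (14.7 to 234.0).

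In mural cells edgeR called 1032 genes in the 4 other libraries, 478 higher and 554 lower, and DESeq2 610. In all 5 libraries edgeR called 0 (768 at an unadjusted p under 0.05) and DESeq2 85. The count was 160 without SuHx 2, 609 without VeNx 1. edgeR called 0 (455 at an unadjusted p under 0.05) when every library was thinned to the 208239 UMIs of VeNx 2, which held 60 mural cells; there 41 of 63 named genes kept their direction, 2 reversed and 20 were not tested. Of 63 named genes, 14 stayed called in every fit that left out a library and 58 kept their direction, the 14 including Ccnd1, Cxcl1, Des, Myl9, Thy1, Tesc and Chrm2. The oxidative phosphorylation list was higher (11 of 44 members called, 28 adjusted over the list alone, adjusted p = 1.73e-13, adjusted p = 0.723 with an estimated correlation). Also higher were smooth muscle contraction (8 of 25 called, 10 higher and 2 lower adjusted over the list alone, adjusted p = 0.000285) and cell cycle (4 of 24 called, 9 adjusted over the list alone, adjusted p = 0.000483). Of 29 lists, 10 passed and 0 passed with an estimated correlation, where the adjusted p of these 3 was 0.723.

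In AT2 cells, which make surfactant, the growth factor gene Ccn2 (log2 fold change 4.23 ± 0.28, edgeR adjusted p = 0.0129), the secreted protein gene Bpifb1 (2.88 ± 0.29, edgeR adjusted p = 0.0408) and the immunoglobulin gene Igha (3.54 ± 0.35, edgeR adjusted p = 0.0408) rose in SuHx. Ccn2 lay at 2.8% of its level in mural cells, Bpifb1 at 2.85% of that in secretory cells and Igha at 0.0152% of that in plasma cells. LOC685963 (4.25) and LOC120098812 (3.64) were also called, and are named after their values were seen because the naming rule leaves out symbols that are only identifiers. These 5 were all that edgeR called in SuHx 1, SuHx 2 and the VeNx libraries, with 1068 at an unadjusted p under 0.05 and 64 called by DESeq2. Under the stricter cell filter edgeR called 2. It called 0 with each library clustered on its own (1051 by edgeR at an unadjusted p under 0.05) and 0 at equal depth (505). The count was 24 without SuHx 1, 0 without SuHx 2 (673 by edgeR at an unadjusted p under 0.05), 68 without VeNx 1 and 244 without VeNx 2. The surfactant list was lower with 0 of 19 members called by edgeR (adjusted p = 1.84e-05, adjusted p = 0.495 with an estimated correlation).

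In alveolar macrophages, the phagocytes of the airspace, the smallest p among genes higher in SuHx were those of Slc1a3 (log2 fold change 2.64 ± 0.20), Cdkn1a (2.40 ± 0.19) and Mcpt2 (7.49 ± 0.61). Among genes lower they were those of Rnase4 (-2.17 ± 0.16), Tac1 (-2.06 ± 0.18) and Trappc9 (-1.68 ± 0.15). Each of the 6 had an edgeR adjusted p of 0.108. Cluster 0 held 99.6% and 98.0% of the alveolar macrophages of SuHx 1 and SuHx 2. Cluster 2, which Tac1 helps to define, held 96.1% and 91.9% of those of VeNx 1 and VeNx 2. Mcpt2 lay at 0.028% of its level in mast cells and Rnase4 at 2.29% of that in fibroblasts. edgeR called 0 genes (2298 at an unadjusted p under 0.05) and DESeq2 738. edgeR called 24 without SuHx 1, 147 without SuHx 2 and 1 without VeNx 1. The extracellular matrix list was higher (adjusted p = 3.21e-06) and the oxidative phosphorylation list lower (adjusted p = 4.3e-05) in SuHx, both with an adjusted p of 0.857 with an estimated correlation.

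Interstitial macrophages, monocytes and T cells were compared to see whether immune cells of the tissue and blood differed. In all 5 libraries, the smallest p in interstitial macrophages were those of Tgfb2 (log2 fold change 2.92 ± 0.53), Nfe2l3 (2.33) and Gata6 (2.76) among higher and Dsc2 (-2.67), Milr1 (-2.88) and Met (-2.75) among lower genes. Each had an edgeR adjusted p of 0.951, and Gata6 lay at 1.55% and Tgfb2 at 3.73% of AT1 cells and Met at 3.51% of AT2 cells. In monocytes of the 4 other libraries, Lyve1 (3.91), Tmem176b (1.32), Cadm1 (-1.72) and Capn3 (-1.13) had an edgeR adjusted p of 0.212 to 0.340. Lyve1 lay at 0.642% of its level in lymphatic endothelial cells, Tmem176b at 7.95% of that in interstitial macrophages and Cadm1 at 8.82% of that in AT1 cells. In T cells Fabp4 (1.85), Tmlhe (-1.91) and Mettl24 (-0.76) had an edgeR adjusted p of 0.132 to 0.698, and Fabp4 lay at 1.83% of its level in endothelial cells. Cpa3 and Mcpt8, each with an edgeR adjusted p of 0.098, lay under 1% of their level in mast cells. In the 4 other libraries edgeR called 1 gene in interstitial macrophages (LOC685963, log2 fold change 5.74 ± 0.32, named after its values were seen; 1021 at an unadjusted p under 0.05, DESeq2 88), 0 in monocytes (1127, DESeq2 101) and 0 in T cells (768, DESeq2 44). In all 5 libraries edgeR called 0 in each (170, 637 and 267 at an unadjusted p under 0.05) and DESeq2 0, 7 and 3. Leaving out VeNx 1 gave 25, 331 and 168 genes in the 3 classes of the 4 other libraries, and leaving out SuHx 1 gave 184, 1 and 39. Leaving out SuHx 2 gave 93, 0 and 29, and leaving out VeNx 2 gave 35, 71 and 0. In T cells the complement list was higher (12 members adjusted over the list alone, adjusted p = 9.2e-19, adjusted p = 0.368 with an estimated correlation). The complement genes C1qa, C1qb and C1qc lead a cluster of interstitial macrophages, whose share was higher in SuHx. RNA carried over from those cells was not tested for this list. In monocytes the interferon response list was lower (0 of 42 members called by edgeR, 2 lower adjusted over the list alone, adjusted p = 4.16e-12, adjusted p = 0.392 with an estimated correlation). Its mean log2 CPM overlapped between the groups, at 5.31 and 4.69 in SuHx 1 and SuHx 2 and 5.21 and 5.83 in VeNx 1 and VeNx 2. The dissociation stress and immediate early list was higher in monocytes (adjusted p = 2.24e-05, adjusted p = 0.504 with an estimated correlation). Its direction reversed without VeNx 1.

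The difference between the changes of endothelial cells and fibroblasts was tested as an interaction in the 4 other libraries, a test chosen after the values were seen. The log2 fold change of 38 of 39 interferon response genes was lower in endothelial cells than in fibroblasts, with a median difference of -1.56 on the log2 scale (camera adjusted p = 1.33e-23, adjusted p = 0.168 with an estimated correlation), and edgeR called 11 of them. That of extracellular matrix genes was higher in endothelial cells, with a median difference of 1.11 on the log2 scale (camera adjusted p = 1.41e-13, adjusted p = 0.168 with an estimated correlation) and 11 members called. Lists of other cell types and of dissociation moved the same way as interferon. The median difference was -2.18 for cytotoxic lymphocyte genes (13 of 13 lower, camera adjusted p = 3.82e-07, adjusted p = 0.272 with an estimated correlation), and -1.19 for alveolar epithelial genes (8 of 8 lower, camera adjusted p = 1.14e-05, adjusted p = 0.286 with an estimated correlation). For dissociation stress and immediate early genes it was -0.656 (29 of 36 lower, camera adjusted p = 3.67e-08, adjusted p = 0.404 with an estimated correlation). The mean log2 CPM of interferon response genes was 4.68 and 4.45 in the endothelial cells of SuHx 1 and SuHx 2 and 5.40 and 5.77 in those of VeNx. In fibroblasts it was 4.33 and 3.96 against 3.55 and 3.76. In all, edgeR called 228 of 13161 genes for the interaction.

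**Figure D4:**
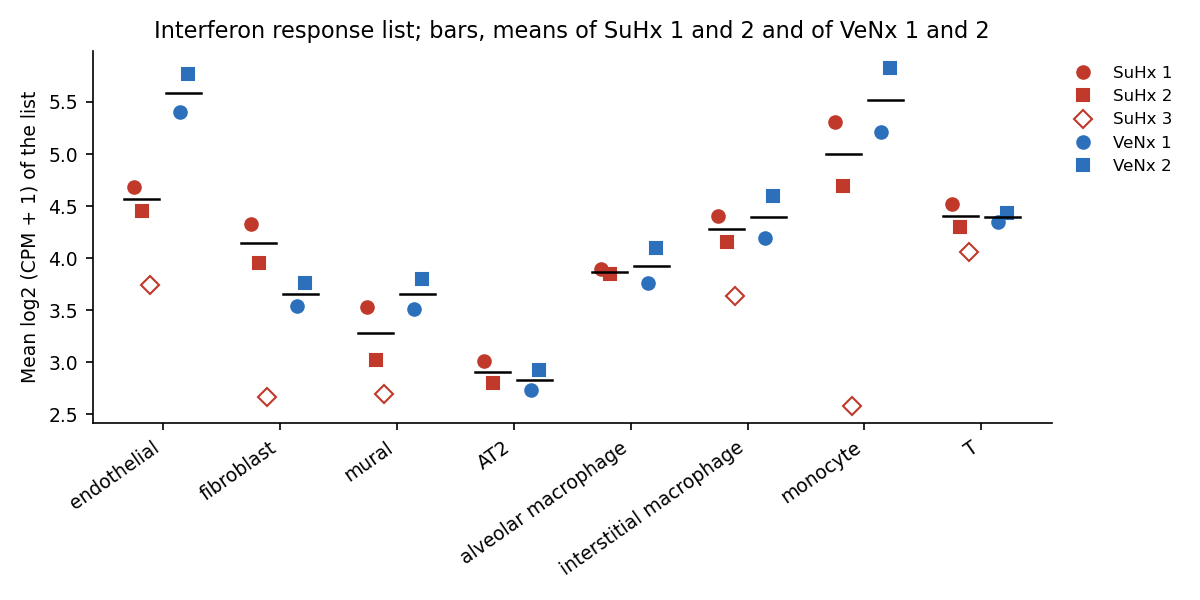
Mean log2(CPM + 1) of interferon response genes per class, 1 point per library (filled red SuHx 1 and SuHx 2, open diamond SuHx 3, blue VeNx), with bars at the means of SuHx 1 and SuHx 2 and of VeNx. Endothelial cells of SuHx 1 and SuHx 2 lie at 4.68 and 4.45, below the VeNx libraries at 5.40 and 5.77.

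In the 8 other fitted classes together, edgeR called 20 genes with all libraries and 17 without SuHx 3, and DESeq2 263 and 297. The neutrophil defensin gene Np4 was at least 165-fold higher in SuHx, a gene named after its values were seen. The count of 17 was 361 without SuHx 1, 445 without SuHx 2, 3333 without VeNx 1 and 764 without VeNx 2. That of 20 was 299 without SuHx 1, 404 without SuHx 2, 1772 without VeNx 1 and 513 without VeNx 2.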

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

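The tests of the library labelled SuHx replicate 3, of the mix of endothelial subtypes, of RNA from other classes among fallen genes and of the interaction were chosen after the result was seen; the other tests were chosen before.

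Heart muscle genes appeared in the library labelled SuHx replicate 3, at a median of 650.2 CPM over 10 genes, in a series labelled as lung. The highest VeNx median of these genes was 0.0744% of that library's. These genes report tissue and not treatment, so they cannot decide on a swap of labels with a VeNx library, which stays open. An effect of the treatment on the lung is argued against, since the highest median in SuHx 1 and SuHx 2 was 0.0559% of that library's. That library also held 0 AT1, AT2, ciliated and secretory cells. A tissue other than lung stays open as a candidate explanation: the median of 10 lung epithelial genes was 0.0359 CPM in that library and 297.1 to 725.8 CPM in the others. Heart of an animal of another sex is 1 such tissue, with Y-linked genes at a median of 0.0838 CPM against 38.3 to 56.0 CPM elsewhere; where a label or tube may have changed, the data do not show.

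Mast cell protease UMIs were higher in SuHx 1 and SuHx 2 than in VeNx in cells of most classes, at 240.7 and 284.4 CPM against 0.778 and 0 CPM in endothelial cells. Doublets with mast cells are argued against as the cause over all classes, since a median of 11.8% of these UMIs lay in cells with at least 10 of them. Doublets stay open in endothelial, fibroblast, mural, interstitial macrophage, AT2 and ciliated cells, where 59.2% to 81.7% of these UMIs did. Free RNA of mast cells or basophils stays open: the largest difference of a gene's share from that in mast cells had a median of 7.55 percentage points over classes, and was highest in NK cells at 15.4. Transcription in every class cannot be told apart from it, as the highest class was 5.24 times the lowest, between the levels named beforehand for either outcome.

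Genes of endothelial cells differed between SuHx and VeNx in the 4 other libraries, 441 of them by edgeR and 111 with called doublets kept. With each library clustered on its own edgeR called 0 (2271 at an unadjusted p under 0.05), and all 70 named genes had the same direction there. RNA from other classes is argued against for the sets of risen and fallen genes as a whole. Of these, 16 of 178, or 9%, and 3 of 263, or 1.1%, lay under 10% of the highest other class. It stays open for the genes under 10%. Among them were the matrix genes Col1a1, Mfap5 and Col5a1, at 1.34%, 2.33% and 8.98% of fibroblasts, and Timp1, at 9.31% of mesothelial cells. The other members of the extracellular matrix list called higher lay above 10%. At equal depth 99.5% of the called genes tested kept over 50% of their log2 fold change. Thinning the sums keeps the expected ratios whatever their cause, so this cannot decide on depth, which stays open. Depth per cell was not evened out. The 312 and 590 endothelial cells of SuHx 1 and SuHx 2 held 2322433 and 4954970 UMIs. The 281 and 237 of VeNx 1 and VeNx 2 held 1284571 and 978226. A changed mix of subtypes and a change inside each kind of cell cannot be told apart: within general capillary cells the median change was 0.958 of that in all endothelial cells, but 1 subcluster there held 18 and 60 SuHx against 91 and 144 VeNx cells and another 32 and 91 against 5 and 7. An effect of SU5416 with hypoxia stays open beside it.

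Between endothelial cells and fibroblasts the log2 fold changes of the 4 libraries differed at the preset correlation, by a test of the difference itself. The median difference of log2 fold changes was -1.559 for the interferon response list and 1.115 for the extracellular matrix list, with a camera adjusted p of 1.33e-23 and 1.41e-13, and 0.168 for both as the adjusted p with an estimated correlation. The difference is not particular to these lists: cytotoxic lymphocyte genes were at -2.176 (13 of 13 lower), alveolar epithelial genes at -1.187 (8 of 8 lower) and dissociation stress and immediate early genes at -0.656 (29 of 36 lower), with an adjusted p of 0.272, 0.286 and 0.404 with an estimated correlation. These results were not weighed further.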

How the results depend on the processing

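The fits on the 4 libraries without SuHx 3 were chosen after the result was seen, as were the C1q cluster alone and the new subclustering; the other alternatives were planned. Among named genes, 2411 values kept their direction and their side of the threshold, 515 lost the call, 157 gained it and 16 reversed; among lists, 498 kept both, 349 lost the call and 13 reversed. The 2411 include uncalled genes that stayed uncalled. They also include 222 values from a minimum of 50 cells per library. Among the classes described in full, that minimum changed only the monocyte fit of all libraries. The cause was not tested where none is given. Where a library left out leaves a group with 1 library, edgeR assumes that it varies like the other group.

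The count of called genes was 0 in all 5 libraries for endothelial, fibroblast, mural, interstitial macrophage, monocyte, T and general capillary cells by edgeR, with the counts at an unadjusted p under 0.05 and by DESeq2 in the report. DESeq2 called 88 endothelial, 4 fibroblast, 85 mural, 7 monocyte, 3 T, 112 general capillary and 263 other genes, and in the 4 libraries 721 endothelial, 160 fibroblast, 610 mural, 88 interstitial macrophage, 101 monocyte, 44 T, 393 general capillary and 297 other genes. It called 64 genes in AT2 cells and 738 in alveolar macrophages.

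Without a filter on low counts edgeR called 43 mural, 117 monocyte, 361 general capillary and 2391 other genes in all libraries, and 2017 endothelial, 739 fibroblast, 1763 mural, 0 interstitial macrophage, 643 monocyte, 398 T, 1178 general capillary and 2477 other genes in the 4 libraries, with 472 in AT2 cells and 947 in alveolar macrophages. Relative log expression size factors gave 6 monocyte genes in all libraries.

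Leaving out a library in all 5 gave 0 to 441 endothelial, 0 to 25 fibroblast, 0 to 1032 mural, 0 to 1 interstitial macrophage, 0 to 765 general capillary, 0 to 234 monocyte and 6 to 1772 other genes, the highest of the first 5 without SuHx 3 and of the last 2 without VeNx 1. The 6 cover B cells and neutrophils alone, the other classes that SuHx 3 entered; with the remaining ones, which it does not change, the sum is 17. In the 4 libraries it gave 201 (without SuHx 1) to 771 (without VeNx 1) endothelial, 0 (without VeNx 1 or VeNx 2) to 133 (without SuHx 2) fibroblast, 160 (without SuHx 2) to 935 (without VeNx 2) mural, 25 to 184 interstitial macrophage, 0 to 331 monocyte, 0 to 168 T, 615 to 1171 general capillary and 361 to 3333 other genes. It gave 0 (without SuHx 2) to 244 (without VeNx 2) genes in AT2 cells and 0 to 147 (without SuHx 2) in alveolar macrophages.

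With called doublets kept edgeR called 111 endothelial, 39 fibroblast and 10 other genes in the 4 libraries and 12 other genes in all. With each library clustered on its own it called 0 endothelial (2271 at an unadjusted p under 0.05), 15 fibroblast, 508 mural and 0 interstitial macrophage genes (652) in the 4 libraries, 0 (1051) in AT2 cells and 10 other genes in all. Of the 70 named endothelial genes, 28 stayed called with doublets kept and 0 with libraries clustered separately, and all 70 kept their direction in both. At equal depth, where VeNx 2 mural cells set 208239 UMIs, edgeR called 40 fibroblast, 0 mural (455 at an unadjusted p under 0.05), 0 interstitial macrophage (408), 268 general capillary and 10 other genes in the 4 libraries, 0 (505) in AT2 cells and 6 other genes in all; fewer UMIs are the alternative's own construction. Of 63 named mural genes 41 kept their direction there, Cox5a (-1.24) and Higd1a (-0.69) reversed, and 20 were not tested. The stricter cell filter gave 2 genes in AT2 cells, resolution 2 gave 54 and the C1q cluster alone 27 interstitial macrophage genes in the 4 libraries. At least 50 cells per library gave 9 other genes in all libraries and 10 in the 4, without mesothelial cells (7 genes called), which could not be fitted there because VeNx 2 holds 47 of them.

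The groups share replicate numbers 1 and 2, which the labels do not describe as pairs. Deviations of same-numbered libraries correlated at 0.015 in endothelial cells, -0.035 in fibroblasts, -0.009 in mural cells, 0.123 in AT2 cells, 0.052 in alveolar macrophages, -0.024 in interstitial macrophages, 0.013 in monocytes and 0.241 in T cells. Replicate number 3 is found in SuHx alone, so its block takes up SuHx 3 wholly and the counts given for all libraries rest on the 4 others. With the replicate block edgeR called 853 endothelial, 39 fibroblast, 1282 mural, 147 interstitial macrophage, 43 T, 711 general capillary and 454 other genes in all libraries, 811 endothelial, 41 fibroblast, 159 interstitial macrophage, 58 monocyte, 44 T and 455 other genes in the 4, 100 in AT2 cells and 2 in alveolar macrophages. With the block 15 lists passed in fibroblasts and 9 in mural cells of all libraries, Eng was at 0.08 and Flt1 at -0.34 on the log2 scale, and the log2 fold change of cell numbers was -0.12 for endothelial cells and 0.38 for alveolar macrophages.

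The difference of shares (SuHx minus VeNx, percentage points) changed sign for classes whose difference lay within the spread of the libraries. Leaving out a library in all 5 gave -0.131 (without SuHx 3) to 10.6 for endothelial cells, -11.3 to 6.67 for alveolar macrophages and -10.8 to 2.66 (without VeNx 2) for T cells. In the 4 libraries it gave -0.886 to 0.624 for endothelial cells, -0.133 to 0.313 for fibroblasts, -0.107 to 0.709 for mural cells, -0.689 to 14.0 for alveolar macrophages and -10.6 to 2.86 for T cells. Leaving out alveolar macrophages gave 0.0613 for endothelial cells, the compartment as total -1.25 for fibroblasts in the 4 libraries and 10.0 for T cells in all, each library clustered on its own 0.0321 for endothelial cells and -0.0432 for fibroblasts, and the stricter filter -0.0014 for fibroblasts. The edgeR test on cell numbers passed for mast cells or basophils in the 4 libraries, with a log2 fold change of 6.60. Among endothelial subtypes, venous cells ranged from -5.40 (without SuHx 3) to 4.25 and were at -1.40 at resolution 2, general capillary cells ranged from -43.2 (without VeNx 1) to -13.2 (without VeNx 2) in the 4 libraries, and aerocytes ranged from -13.6 to 1.24 (without VeNx 1) in the 4 libraries. Subclustered anew without SuHx 3, the difference was -14.6 for general capillary, 12.1 for arterial and -0.274 for venous cells.

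With an estimated correlation 0 lists passed in any of the 8 classes, in all libraries and in the 4, where camera at the preset correlation passed 2 to 24. By fry's test of direction 0 lists passed in any class of all libraries, and in the 4 libraries 1 in endothelial cells, 1 in fibroblasts, 1 in interstitial macrophages and 0 in mural, monocyte and T cells. Its mixed test passed 0 in endothelial, fibroblast, mural, interstitial macrophage and T cells and 2 in monocytes of all libraries, 16 in mural, 3 in interstitial macrophage, 5 in monocyte and 0 in T cells of the 4, and 12 in AT2 cells. Leaving out a library gave 4 to 15 lists in fibroblasts and 2 to 10 in mural cells of all libraries, and 11 to 20 in AT2 cells.

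Lists that reversed did so mostly without VeNx 1, where the adjusted p was 0.186 for cytotoxic lymphocyte genes in fibroblasts (range 0.000426 to 0.371 over the libraries left out), 0.479 for NF-kB genes in mural cells (from 0.00102), 0.486 for cytotoxic lymphocyte genes (from 0.00141) and 0.323 for NF-kB genes (from 0.00308) in AT2 cells, 0.998 for immediate early (from 1.57e-12) and surfactant genes (from 4.98e-05) in alveolar macrophages, 0.330 for immediate early (from 9.63e-27) and 0.596 for endothelial adhesion genes (from 0.000124) in interstitial macrophages, 0.323 for immediate early genes in monocytes (from 5.13e-35) and 0.667 for NF-kB genes in T cells (from 2.87e-13). Without SuHx 2 the adjusted p was 0.627 for endothelial adhesion genes in AT2 cells (from 3.74e-06), also reversed without VeNx 1, and 0.742 for red cell genes in monocytes (range 3.73e-06 to 0.776).

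Uncalled endothelial genes near 0 also reversed on the log2 scale. In all libraries Eng ranged from -0.27 to 0.03, Flt1 from -0.36 (without SuHx 3) to 0.56 and Edn1 from -0.11 to 0.54 with a library left out, and Eng was at 0.11 with doublets kept. In the 4 libraries Eng ranged from -0.12 to 0.17 and was at -0.24 with each library clustered on its own, and Id1 ranged from -0.38 to 0.23 and was at 0.038 with doublets kept. In simulated sums 14.9% of genes changed 2-fold were recovered in endothelial cells of the 4 libraries and 13.4% in alveolar macrophages.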

Other observations

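The tests on neutrophils, mesothelial cells and gene LOC685963 were planned as counts of genes, and the genes named here were chosen after their values were seen.

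In neutrophils of the 4 other libraries, the defensin genes were higher in SuHx: Np4 by at least 165-fold, Defa5 by 586-fold (95% exact counting interval 104.9 to 23190) and RatNP-3b by 1462-fold (262.2 to 57800), and Mbd1 fell by 3.37 on the log2 scale (edgeR adjusted p = 0.00311). Defensin genes are a multigene family whose reads the counting can split, so the level of each gene is uncertain.

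In mesothelial cells Cxcl12 (log2 fold change 3.03), Nnat (2.76) and Fn1 (2.39) rose in SuHx, with an edgeR adjusted p of 0.0335, 0.0188 and 0.0188. edgeR called 7 genes there and DESeq2 60. edgeR called 0 without VeNx 1 (2678 at an unadjusted p under 0.05), 0 without VeNx 2, which held 47 mesothelial cells (1224), 0 with called doublets kept (907) and 0 at equal depth (270). It called 186 without SuHx 1 and 184 without SuHx 2.

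LOC685963, a gene the files name only by its identifier, was called in AT2 cells (log2 fold change 4.25), B cells (4.67), endothelial cells (4.33), fibroblasts (4.57), interstitial macrophages (5.74), mesothelial cells (4.65) and mural cells (5.85) and was higher in SuHx in each. Whether it differs by animal or by treatment was not tested. In fibroblasts it was at 38.5 and 46.9 CPM in SuHx and 1.77 and 1.88 CPM in VeNx.

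UMIs of immunoglobulin genes in endothelial cells were at 72.8 and 40.8 CPM in SuHx and 18.7 and 9.20 CPM in VeNx. Scgb1a1 took 5.72% and 7.95% of all UMIs in SuHx 1 and SuHx 2 and 7.49% and 5.31% in VeNx 1 and VeNx 2.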
